A study of Rattus norvegicus with 8 samples.

How the data were processed

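The data are 8 two-colour NimbleGen arrays of the HELP assay on rat islet DNA, 4 from control and 4 from IUGR litters. Per the labels' protocols, DNA was digested with HpaII or MspI, amplified by ligation-mediated PCR and labelled with Cy3 for MspI and Cy5 for HpaII on every array, so no dye swap balances a dye bias. The deposited scanner values are probe intensity, 1 value per probe and channel, extracted with NimbleScan 2.4.29 from a custom design on the rn4 build, per the file headers. The mismatch column was 0 throughout. The deposited value table holds log2 ratios per fragment, normalized by the authors in a way not given in the sources used here. Set against the log2 ratio of its own array, each deposited log2 column had a slope of 0.956 to 1.06 and a correlation of 0.947 to 0.987, higher than with any other array, so its scale and direction are HpaII over MspI. What stays unknown is its centring and how its MspI term was taken. At chromosome 6, 3664016 to 3664595, chromosome 15, 22841699 to 22841782, and chromosome 8, 74596909 to 74597114, deposited group differences were -1.54, 0.07 and -0.36. From the scanner ratios they were 1.94, 2.08 and -2.24, with MspI differences of -3.48, -2.01 and 1.88. The deposited differences there were close to those of the HpaII signal alone, so more than the centring differed. The deposited medians were 0.11, -0.09, 0.21 and 0.08 in Control 1 to 4 and -0.08, 0.09, 0.23 and 0.43 in IUGR 1 to 4.

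Probe values were taken as log2 intensity without background subtraction. A fragment's value was the median of log2(HpaII / MspI) over its probes, centred on the array's median over tested fragments. A channel counted as above background where it exceeded the median of the 11193 random-sequence control probes plus 2.5 scaled median absolute deviations, and a fragment was tested where MspI did so on all 8 arrays. This kept 580044 of 917288 nuclear fragments (63.2%), with a median length of 467 bp, of which 346650 had 2 probes and 12675 had 1. Mitochondrial fragments stayed out of the tests. Where HpaII was not above background in any sample of the group with the lower ratio, the fold is a bound, computed with HpaII raised to the background threshold of each array.

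Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, IUGR minus Control, two-sided, Benjamini-Hochberg threshold 0.05), per fragment and per 100-kb window of at least 10 fragments. The MspI signal, centred on each array's median, was tested the same way over fragments above background on at least 4 arrays. Values per sample were compared by exact two-sided permutation over 70 splits, whose smallest p is 0.0286. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. The labels give separate litters, and the tests treat the arrays as such. At the 5000 most variable fragments the MspI signals of IUGR 3 and 4 correlated at r = 0.950, so these arrays may not be independent. The p-values may therefore not measure the spread between separate IUGR litters. Whether litters shared parents is not given in the sources used here.

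The loci named in the text are the 10 per direction with the largest difference among called fragments whose groups do not overlap, and the windows the 5 per direction, filled up by the lowest p where too few passed. That rule, the tests and the alternatives below were fixed before the data were examined. The alternatives were normexp correction (offset 50) with loess, quantile normalization, centring and scaling in 20 bins of fragment length, deposited values, mean over probes, no MspI filter, a filter of 5 deviations, array series and replicate number as blocks, each series alone, each replicate left out, array weights, a robust variance model and 500-kb windows. Array series were read from the array numbers, since the file headers gave no batch by date. The density classes, their comparison at like fragment length, the MspI test and the averaging of alike arrays were added after seeing the data.

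The fits were tested on simulated data with 200 changed fragments among 580044, drawn around the real means with the moderated variances. At differences of 0.5, 1, 1.5 and 2 log2 units, 0%, 56%, 98% and 100% of the 50 changed fragments of each size were recovered, and 19 of 146 calls (13.0%) were of unchanged fragments, above the nominal share. Among 14782 windows, changes of 0.1, 0.2, 0.3 and 0.5 log2 units were recovered in 0%, 20%, 70% and 100%, with 11 false among 106 calls. Fragments were not paired with genes in the files, and the gene table held here is of another build, so the planned promoter test, the gene-body contrast and the planned gene lists were not run.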

Results

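DNA methylation was measured in purified pancreatic islets, the clusters of hormone-secreting cells that hold the insulin-producing beta cells, from male Sprague-Dawley rats aged 7 weeks. Islets were pooled, and 4 samples came from control litters of sham-operated dams and 4 from litters of dams whose uterine arteries had been ligated, which restricts fetal growth (IUGR, intrauterine growth restriction). The question was where in the genome islet DNA methylation differs after a growth-restricted gestation. Each sample was run on 1 two-colour array by the HELP assay, in which DNA is cut with HpaII, which cuts CCGG only where the central CpG is unmethylated, or with MspI, which cuts CCGG whether it is methylated or not, and both fragment pools are amplified and hybridised together. A higher log2 ratio of HpaII over MspI therefore marks a less methylated fragment, where the MspI signal is alike. The arrays held 2173621 probes each, for 917288 nuclear HpaII fragments on the rn4 build of the rat genome and for 10 mitochondrial ones. The median MspI intensity ran from 2432 in IUGR 1 to 3472 in IUGR 3 and the median HpaII intensity from 664 in Control 4 to 1049 in Control 3. The number of arrays, 4 per group, limits the precision of each comparison. An annotation of the rn4 build was not used here, so loci are given by position, without the gene or exon they lie in.

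The overall level of islet methylation did not separate the groups. HpaII signal was missing from 25.9% ± 4.00 (SD, n = 4) of the tested fragments in controls and from 25.5% ± 7.47 (SD, n = 4) in IUGR islets, a difference of -0.391 percentage points (exact two-sided permutation test, p = 0.943, adjusted p = 0.943 over 6 array-wide measures, smallest p possible 0.0286). The share was lowest in IUGR 4 at 16.3% and highest in IUGR 2 at 33.1%. It rests on each array's own HpaII background threshold, which was low in IUGR 4 (8.95 log2 units) and highest in IUGR 2 (9.93). Control 4 had the lowest threshold (8.92) and a share of 21.5%, but Control 3, at 9.70, had 23.9%. The share can therefore reflect background as well as methylation. The interquartile range of the log2 ratio, the distance between methylated and unmethylated fragments, was 2.24 ± 0.11 in controls and 2.22 ± 0.19 in IUGR islets (SD, n = 4 each, exact permutation p = 0.886). Mitochondrial fragments, an unmethylated reference within each sample, lay 3.29 ± 0.23 log2 units above the array median in controls and 3.10 ± 0.25 in IUGR islets (SD, n = 4 each, exact permutation p = 0.343, adjusted p = 0.6), at the 97.9 to 99.7 percentile of tested fragments. Fragments of over 5 kb, which amplify poorly and serve as a low-signal reference, exceeded the MspI background in 9.01% to 18.6% of cases, against 68.5% to 87.4% of all nuclear fragments. The arrays fall into 2 series by array number, with 3 controls and 1 IUGR sample in series A and 1 control and 3 IUGR samples in series B. Within series A the share without HpaII signal was 2.32 percentage points higher in IUGR and within series B 2.67 points higher, the opposite sign to the pooled difference, with a single array in 1 arm of each series and so no test. The interquartile range was 0.12 lower within series A and 0.06 lower within series B.

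The HpaII over MspI ratio rose with the local density of CCGG sites in every sample. Fragments with no other array fragment within 1 kb had a median centred log2 ratio of -0.86 ± 0.15 in controls and -0.93 ± 0.09 in IUGR islets (SD, n = 4 each). Those in neighbourhoods of 9 or more fragments, the density typical of CpG islands, stood at 2.37 ± 0.15 and 2.12 ± 0.21. Across all 8 samples, HpaII signal was missing from 50.9% ± 8.14 (SD) of the isolated fragments and from 0.537% ± 0.792 of the densest class. Intermediate classes lay between, at -0.58 and -0.60 for 2 fragments, 0.15 and 0.18 for 3 to 4, and 1.75 and 1.65 for 5 to 8, in controls and IUGR islets. Median fragment length fell from 868 bp in isolated fragments to 146 bp in the densest class, but among fragments of 417 to 467 bp alone the ratio still ran from -0.99 ± 0.10 to 2.69 ± 0.10 in controls and from -1.03 ± 0.03 to 2.64 ± 0.25 in IUGR islets (SD, n = 4 each). The groups differed most in the densest class, by -0.25 log2 units, and no class passed the exact permutation test (p = 0.114 for the densest class, adjusted p = 0.571 over the 5 classes).

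**Figure D1:**
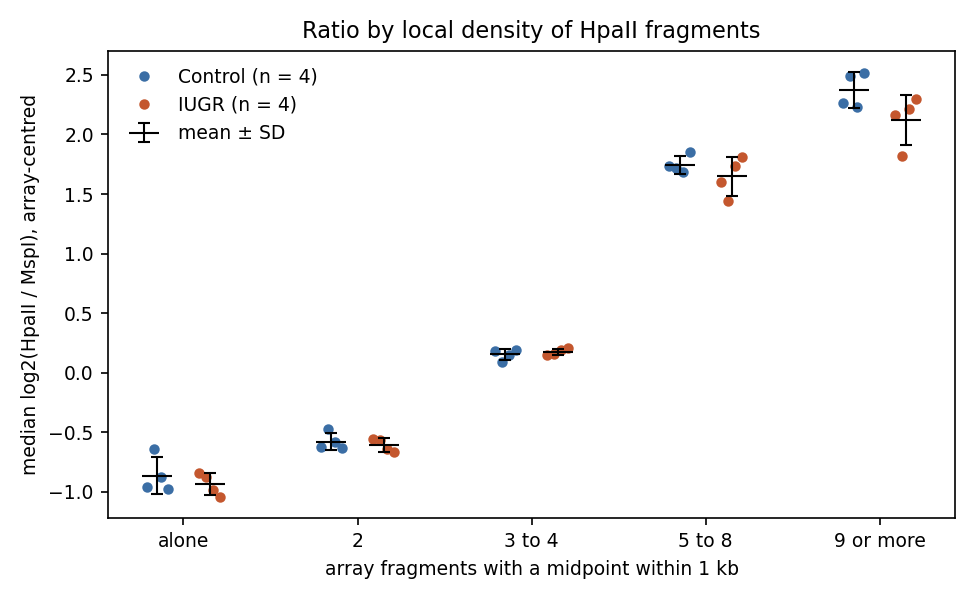
Median log2 ratio of HpaII over MspI, centred on each array's median (y axis), by the number of array fragments with a midpoint within 1 kb (x axis). Each point is 1 sample and the bars give the mean ± SD of 4 control or 4 IUGR samples. The control mean climbs from -0.86 for isolated fragments to 2.37 in the densest class, and the groups overlap in all 5 classes.

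No chromosome as a whole differed between the groups. The ratio of chromosome 2 was among the lower, at -0.29 ± 0.08 log2 units against the remaining fragments in controls and -0.31 ± 0.08 in IUGR islets. That of chromosome 10 was among the higher, at 0.36 ± 0.10 and 0.41 ± 0.04 (SD, n = 4 each). Fragment length, local density and place on the array were not set alike between chromosomes, so these ratios do not rank them by methylation. The largest contrast between groups was that of chromosome 15, at -0.09 log2 units (exact permutation p = 0.143, adjusted p = 0.56). The contrasts went with the place of the fragments on the array: chromosomes 13 to 20 and X, with median array rows of 697 to 705, all lay at -0.04 to -0.09, and chromosomes 6 to 11, with rows of 2089 to 2102, at 0.03 to 0.05. None of the 21 chromosomes had an unadjusted exact permutation p under 0.05.

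At single loci, 255 of 580044 tested fragments differed between IUGR and control islets (limma, Benjamini-Hochberg adjusted p under 0.05). At 118 of them the ratio was higher in IUGR islets and at 137 it was lower. At 40 of the 255 (15.7%) the MspI signal differed more than the HpaII signal, so there the ratio does not read as methylation. HpaII was above background in at least 1 sample of each group at 216 of them, where the median size of the difference was 1.27 log2 units, or 2.41-fold, with a range from 0.88 to 2.80. At the other 39 it was not above background in any sample of 1 group, so the size there is not a measured fold. Among the 216, part of a group can also lack HpaII signal, as did 3 of 4 IUGR samples at chromosome 14, 98266102 to 98266353. The difference there went from -2.27 to -1.62 log2 units with HpaII raised to the background. The median fold of the 216 is therefore not free of this limit. The groups did not overlap at 3.45% of tested fragments, against 2.86% by chance, and at all 255 called loci, which the call itself nearly ensures. An unadjusted p under 0.05 was reached by 35898 fragments, or 6.19%. The called loci made up 5.45 of every 10000 tested fragments in neighbourhoods of 3 to 4 fragments and 2.66 among isolated ones. All 6 called loci in the densest class were lower in IUGR islets. Chromosomes 15 and 16 carried 9.95 and 9.22 called loci per 10000 tested fragments, and chromosome 19 carried 1.57. The split of directions moved with the processing, to 94 higher and 66 lower after normexp correction and loess, and to 123 higher and 217 lower on the deposited values.

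With array series as a block 113 loci were called, and within series A or series B alone 3 each. A single series has 1 array in an arm, and the 255 loci, chosen on these same arrays, differed there by a median of 1.21 and 1.34 log2 units, against 1.28 over all 8 arrays. Averaging IUGR 3 with 4 and IUGR 1 with 2, whose MspI patterns were alike, left 70 calls. Leaving out Control 1, Control 3, IUGR 2 or IUGR 3 left 127, 94, 152 and 125. On simulated data 13.0% of the calls were of unchanged fragments. Those data were drawn independently for each array, without alike arrays or array series, so that share is not an estimate for the 255.

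The loci with the largest rise in ratio in IUGR islets lay on chromosomes 1, 3, 5, 6, 7, 15 and 16. The largest was a 220-bp fragment on chromosome 5, 141278592 to 141278811, where the ratio was -1.15 ± 0.24 in controls and 1.65 ± 0.57 in IUGR islets (SD, n = 4 each), a 6.96-fold difference (limma adjusted p = 7.63e-05). Close by, a fragment starting at 141277709 had an MspI signal 2.04 log2 units higher in IUGR islets. On chromosome 16, 70955541 to 70956344, the ratio went from -0.35 ± 0.15 to 1.96 ± 0.18, with HpaII not above background in 3 of 4 controls (limma adjusted p = 1.91e-05). There too a nearby fragment, starting at 70954176, had a higher MspI signal in IUGR islets, by 1.44 log2 units. A pair of abutting fragments on chromosome 1, 185710194 to 185710868 and 185710869 to 185711694, were 4.92-fold and 5.26-fold higher (limma adjusted p = 0.00934 and 0.0208). Control 1 lay far above the other controls at both, and the call was lost in 7 and 12 of 22 alternatives outside the single series, with adjusted p up to 0.118 and 0.207, at differences of 1.69 to 2.41 and 1.39 to 2.73 log2 units. Elsewhere on chromosome 1, 131409593 to 131410066, the difference was 2.12 log2 units with a standard error of 0.23. The MspI signal there differed by -0.63 log2 units (limma adjusted p = 0.216), and the smallest ratio difference over the alternatives outside the single series was 1.45. The remaining named loci with a higher ratio were chromosome 5, 48503630 to 48503753 (2.07 log2 units), chromosome 15, 22841699 to 22841782 (2.08), chromosome 3, 101637547 to 101637846 (2.09), chromosome 7, 12583454 to 12584928 (1.94), and chromosome 6, 3664016 to 3664595 (1.94). At that chromosome 5 fragment HpaII was not above background in 2 of 4 controls, and scaling in length bins ended the call at 2.05 log2 units (limma adjusted p = 0.0996). The MspI signal there differed by -0.94 log2 units (limma adjusted p = 0.514), and the smallest ratio difference over the alternatives outside the single series was 1.13. On chromosomes 3 and 7 HpaII was not above background in any control, which makes the differences at least 1.76-fold and at least 2.46-fold. At the chromosome 6 fragment the MspI signal was itself 3.48 log2 units lower in IUGR islets, at -3.48 (limma adjusted p = 4.09e-07), HpaII was not above background in any IUGR sample, and the deposited values turned the sign to -1.54. The single-probe chromosome 15 fragment also had a lower MspI signal, by -2.01 log2 units, and was at 0.07 on the deposited values.

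Among the loci with the largest fall in ratio, 3 lay within 1 stretch of chromosome 15. At 23175933 to 23176200 the ratio went from 2.07 ± 0.14 in controls to -1.27 ± 0.32 in IUGR islets (SD, n = 4 each, limma adjusted p = 7.15e-07). HpaII was not above background there in any IUGR sample, so the difference is at least 4.06-fold, and MspI was lower as well, by -1.14 log2 units. At 23184920 to 23185174 the ratio fell by 2.53 on the log2 scale, from 2.19 ± 0.48 to -0.34 ± 0.15, and at 23769703 to 23770224 by 2.30, from 1.59 ± 0.16 to -0.70 ± 0.22. Another chromosome 15 locus, 79145841 to 79146525, went from -0.14 ± 0.33 to -2.31 ± 0.17, with HpaII not above background in 3 of 4 IUGR samples. On chromosome 1, 238963970 to 238964170, the ratio fell by 2.28 (limma adjusted p = 7.63e-05). On chromosome 14 the ratio fell by 2.27 at 98266102 to 98266353, with HpaII not above background in 3 of 4 IUGR samples (-1.62 with HpaII raised to the background). At 47229467 to 47229629 it fell by 2.23 (-1.70 with HpaII raised to the background), and normexp and loess left -0.58 log2 units and no call (limma adjusted p = 0.973). The X-linked fragment at 63546898 to 63547346 fell from 2.86 ± 0.60 to 0.79 ± 0.07, and normexp and loess left -1.32 log2 units and no call (limma adjusted p = 0.0723). On chromosome 8, 74596909 to 74597114, the ratio fell by 2.24 while MspI was 1.88 log2 units higher in IUGR islets (limma adjusted p = 2.35e-05), and on the deposited values the ratio differed by -0.36 and was not called (limma adjusted p = 0.528). The fragment on chromosome 9, 32656942 to 32657264, differed by -2.15 log2 units (limma adjusted p = 0.0165), with HpaII not above background in 3 of 4 IUGR samples (-1.74 with HpaII raised to the background), and leaving out any 1 of 6 samples ended its call at differences of -2.01 to -2.18. The adjusted p rose to 0.363 after normexp and loess (-1.46 log2 units) and 0.808 within series B (-1.84).

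**Figure D2:**
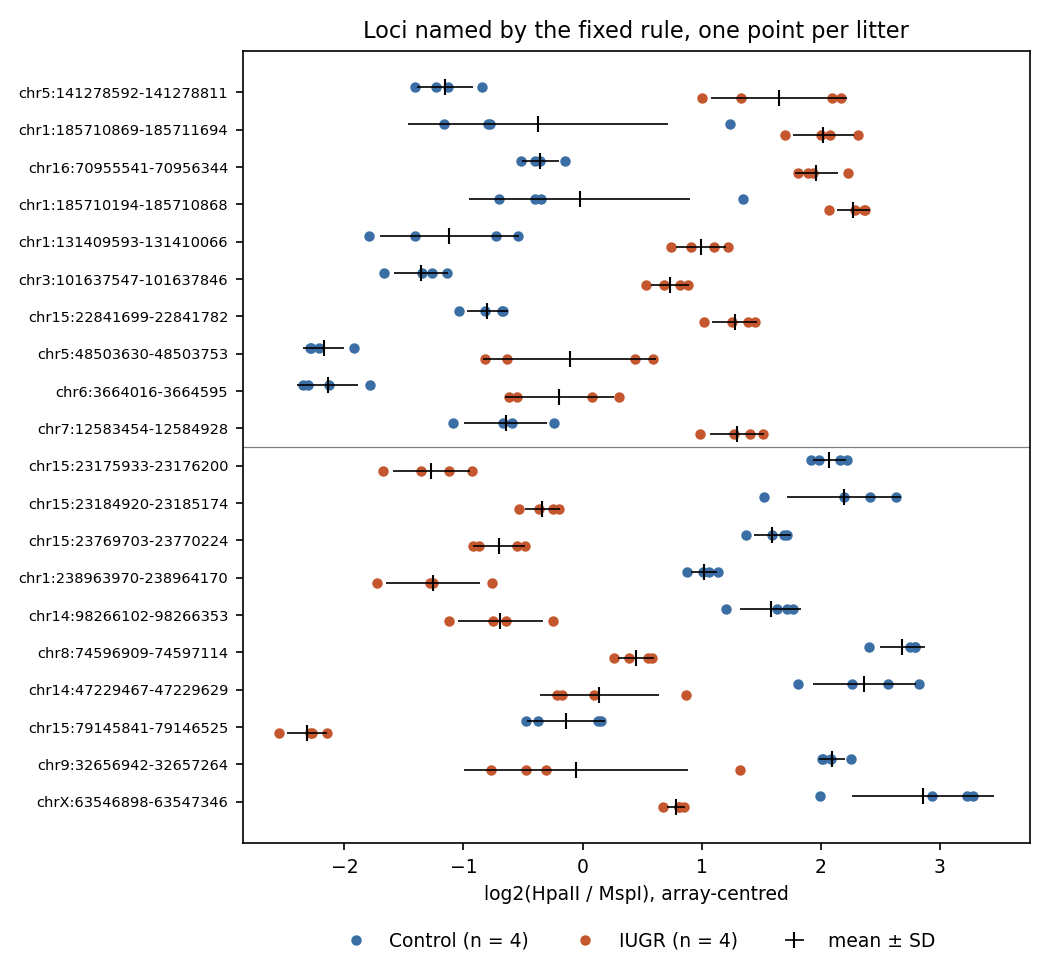
Log2 ratio of HpaII over MspI, centred on each array's median (x axis), at the 20 loci named by the fixed rule (y axis, rn4 positions), with 10 higher in IUGR islets above the line and 10 lower below it. Points are single samples and the ticks and bars give the mean ± SD of 4 samples. No IUGR sample overlaps a control at any of the 20 loci, because the rule took only loci whose groups do not overlap. At chromosome 15, 23175933 to 23176200, HpaII was not above background in any IUGR sample, so its mean of -1.27 is not a measured level. The same holds for the IUGR mean at chromosome 6, 3664016 to 3664595. It also holds for the control means at chromosome 3, 101637547 to 101637846, and chromosome 7, 12583454 to 12584928.

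The called loci were gathered in regions. With gaps of up to 1 Mb, 71 of them lay in 11 regions of 4 or more calls, and 89 stood alone. The region with the most calls, chromosome 15 from 22841699 to 24653925, held 13 called loci among 686 tested, 5 higher and 8 lower in IUGR islets. On chromosome 5, 143964691 to 145626601, 10 of 11 were higher, and on chromosome 8, 10097768 to 11542922, 7 of 8. On chromosome 4, 184081131 to 186812638, 5 were higher and 3 lower, and in a second region of that chromosome, 78625434 to 79909773, 3 and 3.

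The MspI reference signal also differed between the groups, at 1513 of 759741 fragments (limma, Benjamini-Hochberg adjusted p under 0.05), of which 887 were higher in IUGR islets and 626 lower, by a median of 1.35 log2 units. The largest differences were on chromosome 5, 145137312 to 145137846, at 4.08 log2 units, and on chromosome 4, 80754831 to 80755803, and chromosome 12, 20889472 to 20889743, at -3.63 and -3.59. Of the regions above, that on chromosome 15 held 21 of these fragments, that on chromosome 5 held 26, the first on chromosome 4 held 29 and that on chromosome 8 held 16. Of the 255 loci called by ratio, 226 (88.6%) had a fragment with an MspI difference between 5 kb and 1 Mb away, against 38.5% of all tested fragments. Calls numbered 10.3 per 10000 tested fragments within 1 Mb of such a fragment and 0.674 elsewhere. At the called loci themselves 35 had an MspI difference, and the median absolute MspI difference was 0.30 log2 units, against 0.14 over all tested fragments. All but 3 of the 20 named loci had a fragment with an MspI difference within 1 Mb or were one. The 3 were the abutting pair on chromosome 1 and the chromosome 9 fragment. With fragments near MspI differences set aside, these 3 lost their calls at unchanged differences. With array series as a block 831 MspI differences were called, without Control 3 941, and with IUGR 3 and 4 averaged and IUGR 1 and 2 averaged 627.

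**Figure D3:**
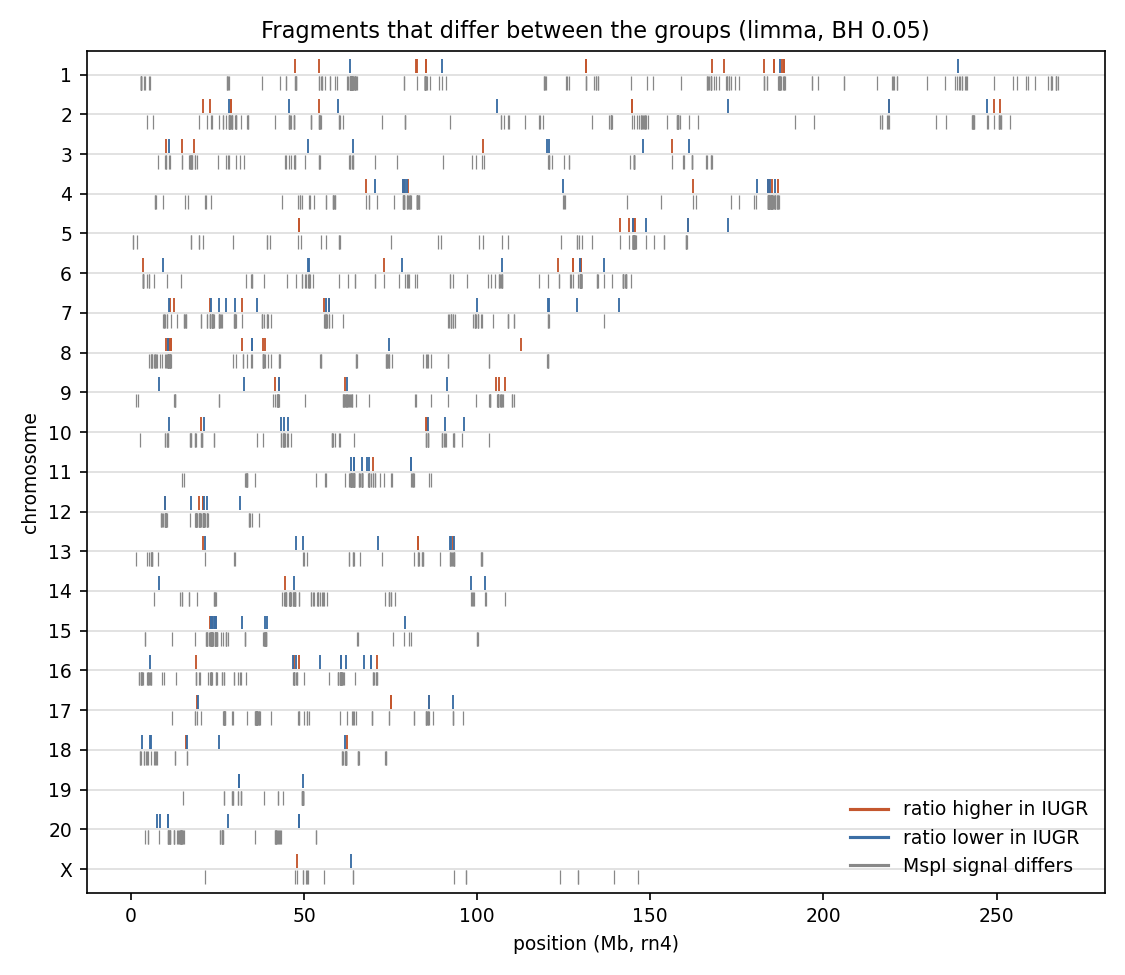
Positions on rn4 in Mb (x axis) of fragments that differed between 4 IUGR and 4 control samples, by chromosome (y axis). Marks above each line are loci called by the HpaII over MspI ratio, coloured by direction, and grey marks below are fragments whose MspI signal differed. Chromosome 15 shows a block of 13 ratio calls over 21 MspI differences.

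The samples were compared by their MspI signal at the 5000 most variable fragments. IUGR 3 and 4 correlated at r = 0.950 and IUGR 1 and 2 at 0.718, while r between those pairs ran from -0.303 to -0.129. Controls correlated with each other at 0.20 to 0.60, and controls with IUGR samples at -0.551 to -0.237. Each fragment was centred on its mean over the 8 arrays, which by itself puts unrelated arrays at an expected r of -0.143. These correlations are across fragments, which are not independent replicates. The mean r was 0.251 within groups and -0.427 between them, a gap that no other of the 35 splits into 4 and 4 reached (exact one-sided permutation test, p = 0.0286, which treats the 8 arrays as exchangeable). Only 7 of the splits keep IUGR 1 with 2 and IUGR 3 with 4, which is too few for a p under 0.05. The other splits count the high r of an alike pair as between groups. MspI signals that differed by over 1.5 log2 units numbered 75 between IUGR 3 and 4 and 651 to 9785 in the 27 other pairs.

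**Figure D4:**
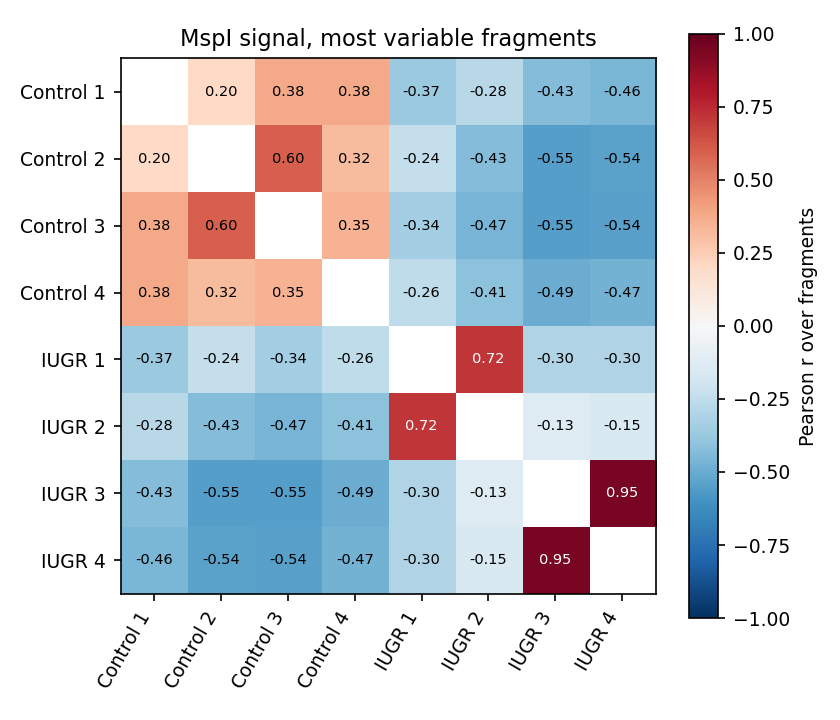
Pearson r across the 5000 most variable fragments between the MspI signals of each pair of arrays, each fragment centred on its mean over the 8 arrays, with sample names on both axes and r by colour and in each cell. IUGR 3 with 4 (0.950) and IUGR 1 with 2 (0.718) stand out, and unrelated arrays are expected at -0.143.

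Across 100-kb windows no regional shift passed the test. Of 14782 windows of at least 10 tested fragments, 0 were called by limma, with 943 at an unadjusted p under 0.05 and a smallest adjusted p of 0.241. The highest-ranked window with a higher ratio in IUGR islets was chromosome 6, 95700001 to 95800000, at -0.13 ± 0.11 in controls and 0.25 ± 0.10 in IUGR islets (SD, n = 4 each), followed by chromosome 17, 75200001 to 75300000, with a difference of 0.35 log2 units. The others of that direction were chromosome 9, 59700001 to 59800000 (0.26 log2 units), chromosome X, 48000001 to 48100000 (0.22), and chromosome 14, 88800001 to 88900000 (0.25). Lower in IUGR islets ranked first chromosome 13, 71300001 to 71400000, at -0.88 ± 0.19 and -1.27 ± 0.15. It was followed by chromosome 9, 43200001 to 43300000 (-0.31 log2 units), chromosome 17, 49000001 to 49100000 (-0.36), chromosome 2, 249900001 to 250000000 (-0.30), and chromosome 9, 62400001 to 62500000 (-0.29). None of these 10 windows passed (limma adjusted p of 0.241 or more). Of the 943 windows with an unadjusted p under 0.05, 899 were lower in IUGR islets. The median window differed by -0.04 log2 units, and whether this offset accounts for the lean was not tested. After quantile normalization 4 windows were called, among them those of chromosome 6 and chromosome 13 at 0.41 and -0.37 log2 units, and 4 without IUGR 4 and 2 without IUGR 3.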

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

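The tests in this part were chosen after the result was seen, except the splits of the MspI calls, the abutting fragments and the count of large MspI differences between arrays.

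In data outside the ratio, the MspI channel, which does not respond to methylation of the CpG, held 1513 fragments that differed between the groups. Of the 35 splits of the 8 arrays, 1 (the real one) gave as many, and the highest of the others gave 758. That count treats the 8 arrays as exchangeable. Only 7 of the splits keep the alike arrays together, IUGR 1 with 2 and IUGR 3 with 4, which is too few for a share under 0.05 (1513 against at most 49 in the others). Of 84 groups of 4 values examined, 4 held a sample whose gap to its nearest neighbour exceeded Dixon's critical value, against 4.2 expected by chance at about 1 in 20. They were Control 1, highest at chromosome 1, 185710869 to 185711694 (gap over range 0.841), Control 2, lowest at chromosome 8, 74596909 to 74597114 (0.883), IUGR 2, lowest in the chromosome 9 window from 43200001 (0.869), and Control 3, lowest in the chromosome 17 window from 49000001 (0.894).

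The ratio calls lie near fragments with an MspI difference, 88.6% of them with one 5 kb to 1 Mb away, a share above all 984 circular shifts of the calls by at least 5000 fragments (highest 57.3%). Another 16 shorter shifts were set aside after the result was seen, because 1 of them moved the calls by 40 fragments, which left them beside the same MspI calls (90.2%). Uneven amplification of single fragments predicts scattered MspI calls, but 53.8% had another 5 to 100 kb away, against at most 19.2% in 1000 draws matched on length and signal. The draws were not matched on region or place on the array, so uneven amplification or hybridisation that varies by region is not excluded. A regional methylation change at intact sites predicts 1 direction per region, but 42.8% of 208 pairs of ratio calls ran opposite ways. Unordered directions would give 49.9% (33.7% to 60.6% in 1000 shuffles). Only 49 of the 1000 shuffles were as low as observed, so neighbouring calls leaned to like directions. In the regions of chromosome 5 (10 of 11 higher) and chromosome 8 (7 of 8), picked for their direction, 23.2% of 69 pairs ran opposite ways, against 52.5% of 139 pairs elsewhere. A regional methylation change is not excluded in these regions. The MspI signal, which does not respond to methylation of the CpG, also leaned to 1 side there. It was higher in IUGR islets at all 16 MspI calls of the chromosome 8 region and at most of the 26 on chromosome 5. Fragments abutting an MspI call differed in its direction in 67.2% of 1294 cases, against 55.3% for fragments 10 places away, but by a median of only 0.15 log2 units, against 1.35 at the calls, so gain or loss of whole CCGG sites may account for part of them, sequence differences between the litters are a candidate explanation for part of the pattern, and an effect of growth restriction on methylation at these loci stays open and untested.

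IUGR 3 and 4 share their MspI pattern, with 75 fragments differing by over 1.5 log2 units against a median of 2240 in the 27 other pairs. The tables argue against array series as the source, since Control 4 and IUGR 2 of the same series correlated with them at most at -0.129, near the -0.143 expected of unrelated arrays after centring. Closely related animals may account for it, as the count of 75 was the lowest of all pairs. Whether 1 DNA preparation was hybridised to both arrays cannot be told apart from this, because their ratios correlated at 0.985 and the next pair at 0.980. With the pair averaged, 168 loci were called.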

How the results depend on the processing

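The settings with IUGR 3 and 4 averaged, with IUGR 1 and 2 averaged as well, without fragments near MspI differences and all those of the MspI count were chosen after seeing the data. The 255 loci became 160 after normexp and loess (93 shared with the 255), 591 without the MspI filter, 141 under the stricter filter (133 shared), 113 with array series as a block (107 shared), 3 within series A, 3 within series B (1 array in an arm, with median differences of the 255 at 1.21 and 1.34 log2 units against 1.28 over all arrays, on which they were chosen), 712 with array weights, 168 with IUGR 3 and 4 averaged, 70 with IUGR 1 and 2 averaged too, 2 without fragments near an MspI difference (24 of the 255 lie among the 356013 left, their differences unchanged, and the adjustment over these keeps 2), and 94 (without Control 3) to 248 (without IUGR 1) with 1 replicate left out. They also fell to 127 without Control 1, 152 without IUGR 2 and 125 without IUGR 3. The count stayed within 1.5 times after quantile normalization (280, of which 243 among the 255), with length bins (202, 172), on the deposited values (340, 124), with the mean over probes (271, 240) and with the robust model (258, 248), so on the deposited values most of the calls were other loci. With the replicate number as a block 478 loci were called, but same-numbered samples correlated at -0.203, 0.249, -0.0873 and 0.293, so the numbers do not pair them, and only replicate 4 correlated best with its own number; the block called 1689 MspI fragments, 1357 of them among the 1513, and changed no call of the windows, the chromosomes, the share without HpaII signal or the interquartile range. The 0 windows became 4 after quantile normalization, 3 with length bins, 1 without the MspI filter, 1 under the stricter filter, 2 with array weights, 3 with IUGR 3 and 4 averaged, and 0 to 4 with 1 replicate left out (2 without IUGR 3, 4 without IUGR 4). The 1513 MspI differences became 831 with array series as a block, 627 with both IUGR pairs averaged, and 941 to 1570 with 1 replicate left out. The difference in the share without HpaII signal (-0.391 points) turned to 1.07 after normexp, 0.590 under the stricter MspI filter, 0.173 at the stricter HpaII background, 2.32 and 2.67 within series A and B, and ran from -2.93 to 2.68 with 1 replicate left out; that of the interquartile range (-0.02) turned to 0.0356 after normexp and loess, 0.0022 with centring in length bins and 0.0061 without the MspI filter, and ran from -0.0841 to 0.0471. None of these had an exact p under 0.05 where a test was run, and no chromosome passed under any setting run. The 20 named loci kept their call in 378 of 413 fits outside the single series, lost it in 34, and turned in 1, chromosome 6, 3664016 to 3664595, at -1.54 on the deposited values; within single series 4 of 40 calls were kept, where each fit had 1 array in an arm, assumed to vary like the others. Apart from fewer fragments or arrays, the cause of these moves was not tested. The deposited values differed from the scanner ratios in more than the centring at some named loci. Scaling within length bins does not bear on the share and fixes the interquartile range, so it was left out there or reduced to centring, and the promoter and gene-list alternatives were not run. HpaII signal over background limits the sizes that can be measured: 39 of the 255 had no sample of 1 group above it. That group is not always the one with the lower ratio, as at chromosome 6, 3664016 to 3664595, it was the IUGR group, with the higher ratio.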

Other observations

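All tests in this part were chosen after the result was seen, except those of the odd split within bins of fragment length.

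The share of tested fragments without HpaII signal fell from 50.9% for isolated fragments to 37.2%, 19.4%, 4.63% and 0.537% as the number of neighbours within 1 kb grew. Short fragments had the higher ratio, as those of 50 to 105 bp stood 2.01 ± 0.22 log2 units above those of 1408 to 9407 bp in controls and 1.82 ± 0.25 in IUGR islets (SD, n = 4 each, exact permutation p = 0.371).

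Splitting the 8 arrays in other ways gave more calls than the real groups in 1 case. Of the 35 splits, 2 gave at least 255 loci, the real one and the split of Control 1 and 4 with IUGR 3 and 4 against the rest, which gave 19840, so chance cannot be excluded on that count alone and the split points to a structure of the samples. For the windows the 0 of the real groups is reached by all 35 splits whatever the data, so that count tests nothing (up to 11 in the others). The odd split takes together the 4 arrays with the widest interquartile range of the ratio, 2.30 to 2.43 log2 units against 2.03 to 2.23. The tables argue against the range alone, or the level by fragment length alone, as its whole source, since 6408 loci were called after quantile normalization (5937 of them among the 19840), 6419 after centring alone within length bins (5240) and 10503 after scaling alone there (9118). Centring and scaling within length bins together left 2 calls, but that changes length and range at once, so they cannot be told apart by it. The median difference of the 19840, which were chosen on these arrays, went from 0.71 (quartiles 0.63 and 0.83) to 0.53 log2 units (0.40 and 0.69) at a standard error of 0.16 both times. The calls ended as the differences shrank and the threshold grew stricter, with 76136 fragments at an unadjusted p under 0.05 in place of 130986, and the source of the split stays open. On the values after both steps the real groups gave 202 loci, the other splits at most 2, and 1 of the 35 splits (the real one) gave as many, if the 8 arrays are taken as exchangeable. Only 7 splits keep IUGR 1 with 2 and IUGR 3 with 4, which is too few for a share under 0.05 (202 against at most 2).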
